A study of Mus musculus with 5 samples.

How the data were processed

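RNA of mouse embryonic stem cells was measured on 5 Affymetrix oligonucleotide arrays with 1 biotin-labelled sample each. J1 cells had been grown on mouse embryonic fibroblast feeders and taken 4 days after transfection with a control siRNA or with an siRNA against Tet1. E14 cells had been grown without feeders, infected with lentivirus carrying a scrambled hairpin or 1 of 2 hairpins against Tet1 (named shRNA3387 and shRNA2863 in the labels), and taken after 4 days of puromycin selection. The groups were taken from the labels, and each holds 1 array. Cell line, feeders and the way of depletion differ together between the J1 and E14 arrays, and this combination is called the system here.

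The deposited values are probe set summaries on a log2 scale. The scale was inferred from the range, since values lay between 1.38 and 14.12 on the 5 arrays. The summary method, background correction and normalization used by the authors to make these deposited log2 values are not given in the sources used here. The medians over all probe sets other than array controls were 3.45 and 3.49 for the J1 control and Tet1 siRNA arrays, and 3.52, 3.46 and 3.49 for the E14 scramble, shRNA3387 and shRNA2863 arrays. The values were used as deposited, with no further normalization. All columns of values could be assigned to a sample by their names. No pair of arrays looked like a copy: at most 14.7% of the non-control probe sets held identical values, and correlations between arrays over them ran from 0.966 to 0.996.

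Probe sets were named from the platform annotation supplied with the values. Of the 45101 probe sets, 64 were array controls, 34958 were listed with 1 gene symbol, 932 with several and 9160 with none, where some array controls carry a symbol and count under both. Of those with 1 symbol, 34754 were matched by Entrez identifier to RefSeq annotation of assembly GRCm38.p6, and 0 symbols changed. The probe set with the highest mean over the 5 arrays stood for its gene, among probe sets with exactly 1 symbol. This gave 18193 genes, of which 13619 were kept because they exceeded the 40th percentile of non-control probe sets on at least 1 array. For each gene named below it was checked whether its other probe sets above the filter had the same sign in the pooled fit. The build behind the platform annotation is not given, so no coordinates are printed, and the chromosome of each gene was used only to group neighbours.

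With 1 array per group, differences between 2 arrays were described by size, with 2-fold as the threshold and no p-value. Tests used limma 3.58.1 in R 4.3.3 with a mean-variance trend, two-sided, with Benjamini-Hochberg adjustment over all kept genes and a threshold of 0.05. The fit over both systems had a system term and a Tet1 term. Its spread came from how the 3 depletions differed among themselves, with 2 residual degrees of freedom. The E14 effect and the difference between the systems were tested in a fit of 4 means, whose single residual degree of freedom came from the 2 hairpin arrays; each lone array was assumed to vary as those do. The p-values measure only the spread between these arrays, which mixes reagent, line and technical variation. No batch is named in the labels, and the number of arrays limits the precision.

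The 20 gene lists, the tests and the rule for naming genes were fixed before the data were examined. The lists held 635 memberships, of which 481 were kept. They were tested in the fit over both systems with camera at a preset correlation of 0.01, again with camera at an estimated correlation, and with fry, each adjusted over the 20 lists. For single pairs of arrays, a list's median was placed among those of 10000 random lists of the same size, matched on mean level in 20 bins. These percentiles describe the arrays and are not tests. The named genes were Tet1 to Tet3, the DNA methyltransferases, Pou5f1, Sox2 and Nanog; the 10 genes each way with the largest smallest difference over the 3 depletions; the 8 largest each way in J1 and with both hairpins; the 5 largest each way between systems and between the control arrays; the 4 largest each way between hairpins; and up to 4 members per list by mean difference. Genes named outside this rule are marked as such.

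Both hairpins share 1 scramble array. The overlap of their differences was therefore set beside 100 simulations of unchanged hairpin arrays and beside the overlap of independent lists. Noise for every simulated array was drawn from the difference between the hairpin arrays, shuffled among genes of like level. The scramble array was thus assumed to vary as the hairpin arrays do. The alternatives tried were quantile normalization, median centring, no filter, a filter at the 60th percentile, the median over a gene's probe sets, limma without a trend, no system term, a 1.5-fold threshold, other set tests and leaving out each array in turn.

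The fits were tested on simulated data with the 13619 genes and gene variances drawn from the fitted prior. The fit over both systems recovered 31 of 100 genes changed 2-fold and 75 of 100 changed 4-fold, with 5 false calls. The E14 fit recovered 0 of 100 at either size, with 0 false calls, so a count of 0 from it does not exclude effects of either size. A list of pluripotency factors shifted by 0.4 on the log2 scale was recovered by camera with the preset correlation, with 0 other lists called, and not with an estimated correlation (adjusted p = 0.109). Camera with an estimated correlation takes its degrees of freedom from the residuals, 2 in the fit over both systems. It therefore had little power to call any list here. The simulated genes varied independently of each other. The simulation therefore cannot show how often the preset correlation calls unchanged lists whose genes vary together. On the real arrays the correlation estimated for the pluripotency factors was 0.56. That estimate rests on 2 residual degrees of freedom, which take in any difference of the Tet1 effect between J1 and E14. It therefore need not mean that unchanged genes vary together.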

Results

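The series addresses how gene expression in mouse embryonic stem cells responds when Tet1, the dioxygenase that oxidizes 5-methylcytosine to 5-hydroxymethylcytosine, is depleted. It holds 5 arrays, 1 for each of J1 cells with control siRNA, J1 cells with Tet1 siRNA, E14 cells with a scrambled hairpin, and E14 cells with Tet1 shRNA3387 or shRNA2863. J1 and E14 are established mouse embryonic stem cell lines. No group has a replicate, so differences between single arrays carry no error. Values are log2 probe set summaries, and differences are log2 of depleted minus the control of the same system.

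Tet1 itself was lower on all 3 arrays labelled as depleted. Its brightest probe set read 10.85 with control siRNA and 8.31 with Tet1 siRNA in J1 cells, 5.82-fold lower, or 17.2% of the control level. In E14 cells it read 10.95 with the scrambled hairpin, 9.24 with shRNA3387 (3.27-fold lower, 30.6% left) and 10.06 with shRNA2863 (1.85-fold lower, 54.0% left). The second brightest Tet1 probe set differed from its control by -2.84, -2.40 and -1.18 for J1 siRNA, shRNA3387 and shRNA2863, and the third by -1.52, -1.80 and -1.01. The Tet1 signal with shRNA3387 was below that with shRNA2863 in these 3 probe sets, by differences of -0.82, -1.22 and -0.79. The remaining Tet1 probe set lay under the filter level on all arrays, between 2.25 and 2.28. In the limma fit over both systems Tet1 differed by -1.83 ± 0.43 (SE, 3 depleted and 2 control arrays). Its unadjusted p was 0.0144, and the Benjamini-Hochberg adjusted p from limma was 0.7.

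**Figure D1:**
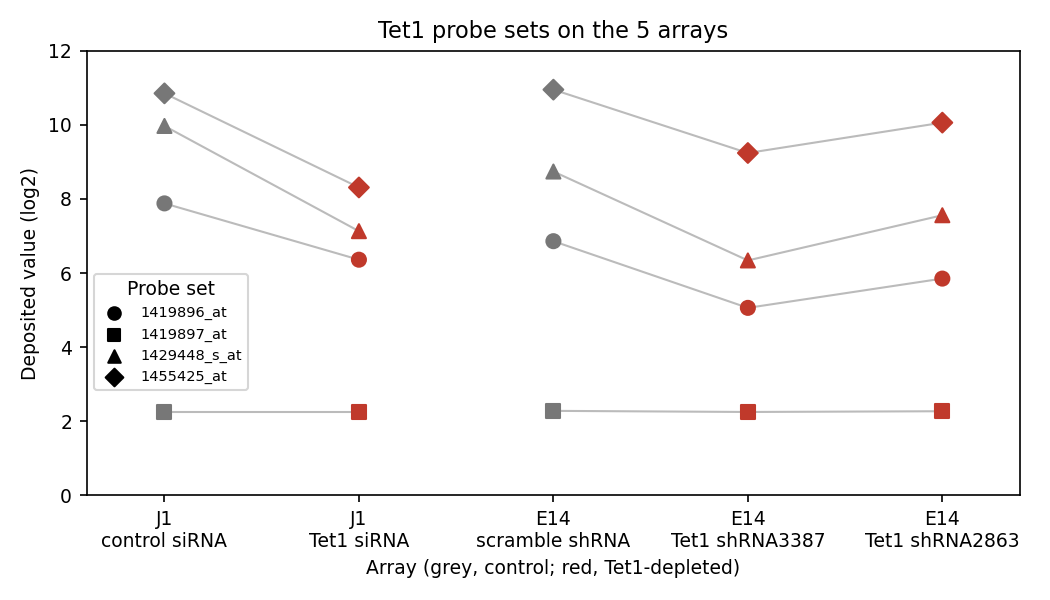
Log2 values (vertical axis) of the 4 Tet1 probe sets on each of the 5 arrays (horizontal axis), with controls in grey and depleted arrays in red, and lines joining arrays of 1 system. In the brightest probe set the depleted arrays read 8.31, 9.24 and 10.06 against 10.85 and 10.95 in the controls.

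Among the related enzymes, Tet2 was 2.19-fold lower in J1 cells with Tet1 siRNA (8.03 against 6.90) and differed by -0.19 and -0.17 with shRNA3387 and shRNA2863. Tet3 was under the filter level at 2.23 to 2.25 on the 5 arrays and was not kept. The maintenance methyltransferase Dnmt1 differed by -0.08, 0.05 and 0.10 in J1 siRNA, shRNA3387 and shRNA2863, and neither of its 2 other probe sets had the sign of its pooled difference of 0.01. The de novo enzyme Dnmt3a differed by -0.07, 0.11 and -0.30, Dnmt3b by -0.07, 0.53 and 0.13, and their cofactor Dnmt3l by -0.39, -0.03 and -0.58. Over the list of Tet and DNA methylation genes (19 kept), which includes the base-excision and methyl-binding proteins, median differences were -0.12, 0.02 and -0.05, and camera did not call it (adjusted p = 0.934). The methyl-binding protein Mbd2 differed by 0.88, -0.03 and 0.63.

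The core pluripotency regulators stayed highly expressed. Pou5f1, which encodes Oct4, differed by -0.46, -0.26 and -0.36 in J1 siRNA, shRNA3387 and shRNA2863, with a pooled difference of -0.37 ± 0.07 (SE; limma adjusted p = 0.7). Sox2 differed by -0.35, 0.06 and -0.03, and Nanog by -0.88, -0.10 and 0.02, so that Nanog was 1.84-fold lower in J1 and within 1.07-fold of its control with both hairpins. The difference of the Nanog effect between the systems was 0.84 ± 0.13 (SE), with a limma adjusted p of 0.344.

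Few genes differed the same way in all 3 depletions. At least 2-fold higher in each was 1 gene, Mex3b, an RNA-binding protein, with differences of 1.01, 1.20 and 1.05. At least 2-fold lower in each were 5 genes: Spink1, a secreted trypsin inhibitor (-1.84, -2.24 and -3.36); Gbx2, a homeobox factor of the anterior hindbrain and a target of LIF signalling in stem cells (-1.29, -1.32 and -1.25); Marf1, an RNA regulator of the oocyte (-1.15, -1.50 and -1.29); the Ras-family GTPase Mras (-1.15, -1.50 and -1.21); and the cytokine Ltb (-1.15, -1.08 and -1.12). Spink1 read 4.04 with control siRNA and 2.20 with Tet1 siRNA, under that array's filter level of 3.06, so its place among the 5 genes rests in J1 on signal that is hard to tell from background. Independent lists of the sizes seen would share 0.0103 genes, a figure that leaves out the scramble array shared by the hairpins. The same count over the depletions left was 9 without shRNA2863, 11 without shRNA3387 and 73 without either J1 array.

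The next largest shared differences were of at least 0.72 in size in each depletion. Higher were Sos2, an exchange factor for Ras (0.85 in J1, and 1.06 as the mean of both hairpins), the kainate receptor subunit Grik3 (0.88, 0.85 and 1.09), the tight junction protein Marveld2 (0.77, 1.19 and 0.98), the phosphatase Ptpn13 (0.76, 1.67 and 0.86), Tmem164 (0.75, 1.87 and 1.22) and the ubiquitin ligase Rnf128 (1.18, 0.77 and 0.72). Atxn1, Stxbp5 and Npnt also ranked here with pooled differences of 1.01, 0.86 and 0.78, but the other probe set of Atxn1 and both others of Stxbp5 pointed the opposite way, as did 1 of 2 for Npnt. As the median over all probe sets of a gene, the pooled difference was -0.12 for Marf1, -0.19 for Atxn1, -0.24 for Stxbp5, 0.00 for Npnt, 0.46 for Grik3, 0.60 for Ptpn13 and -0.63 for Plekhg1, and 5 genes were 2-fold different the same way in all 3 depletions. Lower were Vmac (-1.39, -1.01 and -0.92), the transglutaminase Tgm1 (-0.89, -1.63 and -1.22), the acyltransferase Gpat2 (-0.87, -1.28 and -1.08), Plekhg1 (-0.86, -1.78 and -1.31) and the mitochondrial folate enzyme Aldh1l2 (-0.89, -1.20 and -0.86). For Marf1, 1 of 2 other probe sets had the same sign, and for Mras and Rnf128 the only other one did.

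No gene passed the limma test over both systems. The count at an adjusted p under 0.05 was 0 of 13619, with a lowest adjusted p of 0.7. An unadjusted p under 0.05 was reached by 936 genes (390 higher, 546 lower), where chance gives 681 if the spread is estimated correctly. When other arrays were called the control, 1 in each system, the unadjusted count ran from 308 to 735. Among the genes 2-fold lower in each depletion, the smallest pooled errors were those of Ltb (-1.12 ± 0.07 SE, unadjusted p = 1.24e-04) and Gbx2 (-1.29 ± 0.10 SE, unadjusted p = 2.52e-04), both with adjusted p = 0.7 in limma. The fits without a trend and without the system term also called 0 genes.

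In J1 cells, Tet1 siRNA was accompanied by lower levels of all 34 kept pluripotency factors and higher levels of most trophectoderm markers. Trh, the thyrotropin-releasing hormone precursor, was 20.4-fold lower (7.53 against 3.18). Lefty2, a Nodal antagonist and target, was 4.63-fold lower, the activin subunit gene Inhbb 4.50-fold and the homeobox factor Otx2 4.08-fold. The placental gene Plac1 was 6.50-fold higher (4.36 against 7.06) and the transcriptional coactivator Cited1 4.35-fold higher. In all, 64 genes were at least 2-fold higher and 150 at least 2-fold lower, and the middle 95% of differences ran from -0.80 to 0.62.

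Other genes at the top of this comparison were the NADPH oxidase Nox4 (4.32-fold higher), the phosphatase Dusp18 (4.26-fold), the transcription factor Cebpa (4.00-fold), Igfbp6 (3.71-fold), the leukotriene receptor Cysltr1 (3.46-fold) and the nuclear RNA Malat1 (3.32-fold, all 6 other probe sets with the same sign in the pooled fit, and 0.29 on the log2 scale as the median over probe sets). Besides Tet1, the meiotic cohesin Smc1b was 5.46-fold lower, Tsx 4.38-fold and Notch4 4.03-fold. Smc1b, Tsx and Notch4 read 2.40, 2.45 and 2.76 with Tet1 siRNA, and Dusp18 and Cebpa 2.78 and 2.39 with control siRNA, under the filter level, so their folds rest on signal that is hard to tell from background. With the median over all probe sets of a gene, the J1 difference was -1.06 for Inhbb, -0.66 for Notch4, 0.96 for Dusp18 and 1.10 for Cysltr1, and the J1 split turned to 131 higher and 100 lower. A single pair of arrays gives these differences no replicate check.

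By the fixed lists, all 34 kept pluripotency factors were lower with Tet1 siRNA, 13 of them by at least 1.5-fold, with a median difference of -0.49 that lay below all 10000 level-matched random lists. The naive-state factors Tcl1, Esrrb, Tbx3 and the RNA-binding protein Lin28a differed by -1.46, -1.21, -0.52 and -0.52. Trophectoderm markers had a median of 0.42, above all 10000 random lists, with 21 of 26 higher and 6 by at least 1.5-fold; besides Plac1, Esx1 differed by 0.51, Rhox9 by 0.48 and Igf2 by 0.42. Primitive endoderm markers had a median of 0.14, with 5 of 10000 random lists at or above it and 16 of 23 higher, 3 of them by at least 1.5-fold. Integrated stress response genes had a median of -0.40, below all random lists, with 11 of 28 at least 1.5-fold lower, among them the glutathione-degrading enzyme Chac1 (-1.57) and Sesn2 (-1.29), while Asns differed by -0.42 and Atf3 by 0.21. Fibroblast feeder markers, chosen for the other cell type in the J1 cultures, had a median of 0.01 (percentile 75.4 of the random lists), with Col1a1 at -0.50, Cd44 at 0.25, Tgfbi at -0.09 and Acta2 at -0.13. Only 10 of these 30 markers were higher in J1 control than in feeder-free E14 scramble cells. Genes with a mean log2 value over 6 had a median difference of -0.09 on this pair of arrays.

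In E14 cells, both hairpins were accompanied by higher Sox3, a neural and epiblast factor, and lower alpha globin and imprinted Rian. Sox3 was 7.36-fold higher with shRNA3387 and 3.46-fold higher with shRNA2863. Hba-a2 was 6.54-fold and 6.77-fold lower, Spink1 4.72-fold and 10.3-fold lower, and Rian, a noncoding RNA of the Dlk1 and Meg3 cluster, 2.69-fold and 5.50-fold lower. At least 2-fold the same way with both were 32 genes higher and 41 lower, 73 in all. The split was 25 higher and 55 lower after quantile normalization and 45 higher and 36 lower after median centring, so the larger direction depended on the scaling.

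Further genes higher with both hairpins were the adenylate cyclase Adcy7 (1.85 with shRNA3387 and 1.74 with shRNA2863), the imprinted antisense RNA Kcnq1ot1 (1.84 and 1.57), the kinase Camk1 (1.54 and 1.51), Rps6kc1 (1.63 and 1.39), the hyaluronan receptor Cd44 (1.38 and 1.41) and the growth factor Ptn (1.60 and 1.35). Insyn2a differed by 1.98 and 1.48, but its other probe set had the opposite sign in the pooled fit. Further genes lower were the myosin Myo1f (-2.46 and -1.68), 4930579H20Rik (-1.72 and -1.66), the RNA-binding protein Raly (-1.62 and -1.59) and the ribosomal protein Rpl27a (-1.73 and -1.59). Rps6kc1 read 2.63 with the scrambled hairpin, and 4930579H20Rik 2.98 and 3.04 with the Tet1 hairpins, under the filter level. Vapb differed by -2.03 and -1.43, and neither of its 2 other probe sets had that sign in the pooled fit. As the median over all probe sets of a gene, the mean E14 difference was 1.16 for Sox3, 0.59 for Adcy7, 0.37 for Cd44, 0.02 for Kcnq1ot1, -0.04 for Ptn and -0.06 for Insyn2a, and it was -0.84 for Rian, -0.82 for Raly, -0.84 for Rpl27a and -0.02 for Vapb.

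Tet1, 1.85-fold lower with shRNA2863, was not among the 73 genes. Both hairpins were compared with the same scramble array. Unchanged hairpin arrays simulated against 1 shared control gave a mean of 26.8 such genes and at most 40 in 100 simulations, and independent lists 1.46. Across genes the differences of the hairpins correlated at r = 0.62, with 0.50 simulated, and their covariance was 0.065 with 0.041 simulated, leaving 0.024. The simulated noise came from the hairpin pair, so a scramble array that varied more than the hairpin arrays could also give this excess. Limma called 0 genes in E14 (lowest adjusted p = 0.342), with 1500 at an unadjusted p under 0.05, 604 higher and 896 lower.

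The hairpins also differed from each other, with 90 genes at least 2-fold higher and 47 at least 2-fold lower with shRNA3387 than with shRNA2863. The largest was Fgf5, a marker of the primed epiblast, which read 2.91 with the scrambled hairpin, 6.65 with shRNA3387 and 2.89 with shRNA2863. Slc35d3 read 2.66, 5.66 and 2.63 on the same arrays, and the transcription factor Myb 4.29, 6.86 and 4.50. Cystm1 was 5.31-fold higher with shRNA3387 than with shRNA2863. Lower with shRNA3387 than with shRNA2863 were the actin Acta1 (5.90-fold), the Wnt target Sp5 (4.26-fold), the small heat shock protein Cryab (3.76-fold) and the germ cell factor Sohlh2 (3.56-fold). These are differences between 2 single arrays. Fgf5 and Slc35d3 were under the filter level with the scrambled hairpin and with shRNA2863, so their folds rest on signal that is hard to tell from background.

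The genes with the largest differences in J1 cells had mostly small differences in E14 cells, as Plac1 (2.70 in J1 and a mean of 0.05 in E14) and Nox4 (2.11 and -0.03) did. Across the 13619 genes, J1 differences correlated with the mean E14 differences at Pearson r = 0.11 and Spearman rho = 0.07, with r = 0.05 for shRNA3387 alone and 0.15 for shRNA2863 alone; these correlations are across genes, which are not independent replicates. Of the 73 genes found with both hairpins, 43 had the same sign in J1 and 30 the opposite, 19 had the same sign and at least 1.5-fold, and the median difference signed by the E14 direction was 0.07 (percentile 99.8 of 10000 random lists). Those random lists were matched on mean level but not on how much the genes vary. Effects higher in E14 than in J1 were led by Trh (difference of effects 3.69 ± 0.42 SE), the gonadal factor Dmrt1 (2.53 ± 0.64), Smc1b (2.43 ± 0.04), Kcnq1ot1 (2.32 ± 0.28) and Myb (2.24 ± 2.11). Effects lower in E14 were led by Hba-a2 (0.26 in J1 and a mean of -2.74 in E14), Plac1 (-2.65 ± 0.80), Nox4 (-2.14 ± 0.26), Dusp18 (-2.12 ± 0.06) and Myo1f (-2.08 ± 0.70). Limma called 0 of these differences (lowest adjusted p = 0.332), with 1888 genes at an unadjusted p under 0.05. The errors come from the hairpin pair alone. Smc1b and Dusp18 were under the filter level on all E14 arrays, so their differences of effects with small errors restate the J1 differences, and Hba-a2 was under it in J1 control cells at 2.90.

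**Figure D2:**
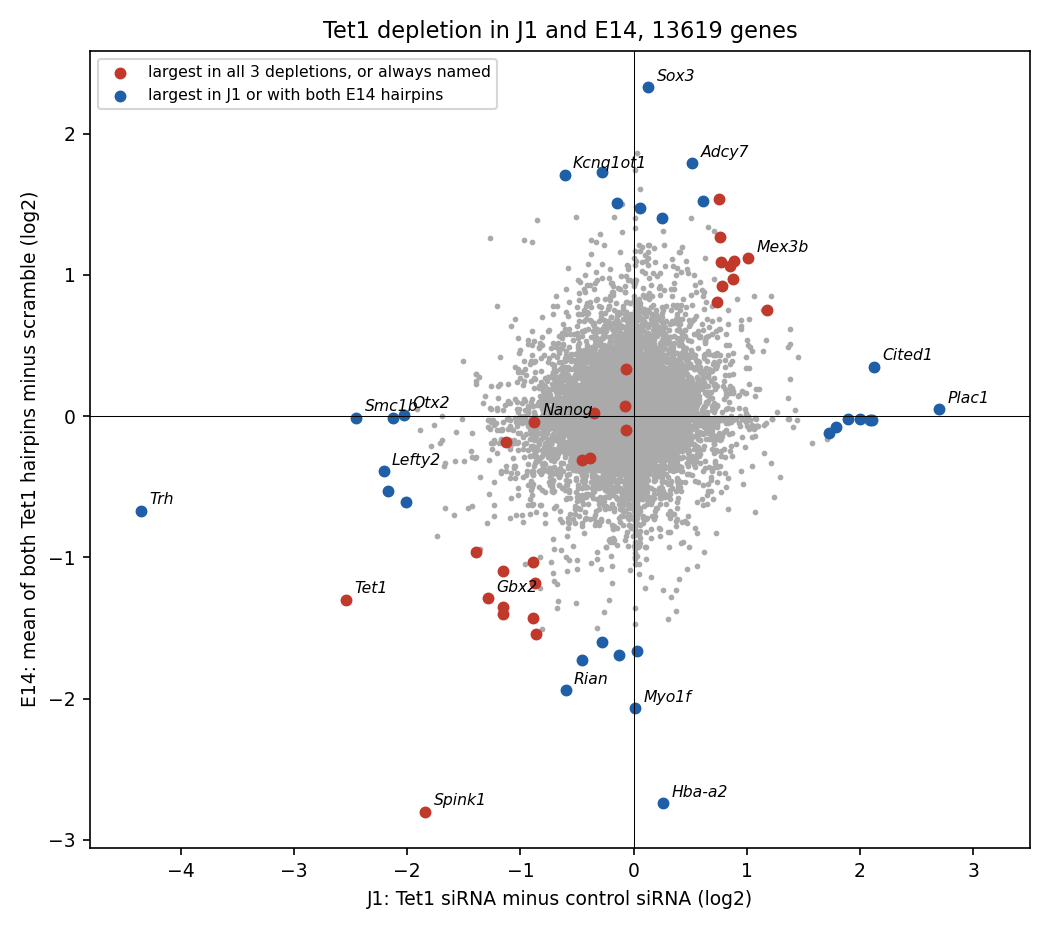
Log2 difference of each of 13619 genes in J1 (Tet1 siRNA minus control, horizontal axis) against the mean of both E14 hairpins minus scramble (vertical axis), 1 point per gene, with named genes shared by all 3 depletions or always named in red and those largest in 1 system in blue. Trh and Plac1 lie along the J1 axis, Hba-a2 and Sox3 along the E14 axis, and across all genes r = 0.11.

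Before any depletion the control arrays of the systems already differed widely, by at least 2-fold at 1138 genes (479 higher and 659 lower in E14). Hprt, the purine salvage enzyme, read 10.91 in J1 and 4.43 in E14, and the phosphatase Dusp5 7.05 and 2.75, the latter under the filter level. The imprinted gene Nnat was 20.7-fold lower in E14 and 3830417A13Rik 14.4-fold, while the adhesion protein Pecam1 read 7.44 in J1 and 3.44 in E14. Higher in E14 were Pik3cd (64.4-fold), Snord104 (40.2-fold), 1700097N02Rik (21.6-fold), Mid1 (19.8-fold) and Spink1 (18.6-fold). Each is a difference between 1 array and 1 array and rests on 1 probe set. Other probe sets of these genes, where present, were not compared between the control arrays.

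Over all 3 depletions, 6 of the 20 fixed lists passed camera with the preset correlation, 5 lower and 1 higher, and 0 passed with an estimated correlation or in fry. On 2 residual degrees of freedom camera with an estimated correlation had little power, so its adjusted p does not by itself count against a list. With either J1 array left out, 0 lists passed, and the pluripotency median was -0.10 or -0.09. Without the scramble array, neuroectoderm, interferon and integrated stress response genes no longer passed (adjusted p = 0.314, 0.314 and 0.124), nor did integrated stress response genes without shRNA2863 (adjusted p = 0.278). Primitive endoderm markers (0.14, adjusted p = 0.012) and germline genes (-0.19, adjusted p = 0.0306) passed without the scramble array, and germline genes (-0.17, adjusted p = 0.0376) without shRNA2863. Pluripotency factors were lower (medians -0.49, -0.13 and -0.04 in J1 siRNA, shRNA3387 and shRNA2863; adjusted p = 6.81e-07, and adjusted p = 1 with an estimated correlation), with 17 of 34 lower in all 3. Trophectoderm markers were higher over the fit (0.42, -0.04 and 0.00; adjusted p = 0.0214, and adjusted p = 1 with an estimated correlation), with 4 of 26 higher and 3 lower in all 3, and the median with each hairpin was at or below 0. Integrated stress response genes were lower (-0.40, 0.04 and -0.20; adjusted p = 0.0214, and 1 as the adjusted p with an estimated correlation), with 7 of 28 lower in all 3 and the shRNA3387 median above 0.

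Neuroectoderm markers were lower over the fit, with medians of -0.11, -0.10 and -0.11 and 12 of 22 lower in all 3 (adjusted p = 0.0197, and adjusted p = 0.855 with an estimated correlation). The neuroectoderm medians depended on dim genes: the pooled median was -0.11, -0.04 without a filter and -0.36 with the filter at the 60th percentile, and the J1 median ran from -0.40 to -0.01. Without a system term neither neuroectoderm (adjusted p = 0.0969) nor trophectoderm markers (adjusted p = 0.675) passed. Besides Gbx2, Neurod1 differed by -0.96, -0.72 and -1.38, the eye and forebrain factor Pax6 by -0.73, -0.72 and -1.34 (its other probe set with the opposite sign), and the neuronal tubulin Tubb3 by -0.48, -0.81 and -0.62. Adjusted over the list alone, 1 gene passed in limma, Gbx2 (adjusted p = 0.00555), against 0 over all genes tested, and for each of the other 19 lists 0 genes passed adjusted over the list alone. The fry test gave an adjusted p of 0.275 for a shift one way and 0.00333 for change in either direction.

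Proliferation genes were lower by a small amount, with medians of -0.12, -0.08 and -0.12 and 18 of 38 lower in all 3 (adjusted p = 0.002, and adjusted p = 0.855 with an estimated correlation; median over probe sets -0.07, adjusted p = 0.158). The cell cycle inhibitor Cdkn2a differed by -0.67, -1.33 and -1.30, the mitotic kinesin Kif11 by -0.20, -0.41 and -0.40 and Ccne1 by -0.43, -0.22 and -0.29, while Ccne2 differed by 0.66, 0.68 and 0.46. Cdkn2a restrains division, against the name of its list. Interferon response genes had medians of -0.19, -0.08 and -0.03 with 8 of 22 lower in all 3 (adjusted p = 0.0197, and adjusted p = 1 with an estimated correlation), and the J1 median ran from -0.42 to -0.01 over the filters. There Xaf1 differed by -0.68, -1.52 and -1.20, Stat2 by -1.02, -0.05 and -0.97, Parp14 by -0.95, -0.41 and -0.44 and Trim25 by -0.66, -0.40 and -0.47. Of other probe sets, the only one for Ccne1 and for Sesn2 had the opposite pooled sign, as had 1 of 2 for Esrrb, Kif11 and Trim25 and 1 of 4 for Mtf2.

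The other lists did not pass camera. Nodal and Activin pathway genes had medians of -0.26, 0.21 and 0.09 (adjusted p = 1), with 3 of 18 at least 1.5-fold lower in J1, Lefty1 at -1.13, -0.05 and -0.73 and the activin-binding protein Fst at -0.33 in J1 and a mean of 1.02 in E14. Primed epiblast markers had medians of -0.18, 0.16 and -0.02 (adjusted p = 1), where Sox3 stood against Zic2 (0.01, -1.35 and -1.59) and Otx2 (-2.03, 0.18 and -0.15). Fgf5 was higher with shRNA3387 alone (0.03, 3.74 and -0.02). Primitive endoderm markers had medians of 0.14, -0.05 and -0.03 (adjusted p = 0.792), with Lama1 at -0.54, -0.67 and -1.17 and P4ha2 at 0.50, 0.50 and 0.80. Mesoderm and primitive streak markers lay at 0.01, -0.07 and -0.01 (adjusted p = 0.792), Hox genes at 0.01, -0.04 and -0.01 (adjusted p = 0.984) and two-cell-like genes, with 7 kept, at 0.17, -0.51 and -0.01 (adjusted p = 0.984). Methylation-controlled germline genes had medians of -0.19, -0.03 and 0.19 (adjusted p = 0.934), and the synaptonemal protein Sycp1 differed by 0.13, 0.82 and 1.33.

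Imprinted genes had medians of 0.01, -0.03 and -0.10 (adjusted p = 0.984), and paternally expressed Peg3 differed by -0.21, -0.95 and -0.80. Polycomb subunits had medians of -0.05, 0.03 and 0.05 (adjusted p = 0.984), with the PRC2 accessory protein Mtf2 at -0.49, -0.62 and -0.41. Hypoxia and glycolysis genes had medians of -0.13, 0.17 and -0.07 (adjusted p = 1), with the phosphofructokinase Pfkp at -1.39, -0.25 and -0.34. Targets of p53 had medians of 0.01, -0.19 and 0.01 (adjusted p = 1), fibroblast feeder markers 0.01, -0.08 and -0.01 (adjusted p = 0.984) and ribosomal proteins -0.01, -0.03 and -0.01 (adjusted p = 0.984). In fry, change in either direction also passed for proliferation genes (adjusted p = 0.0143), primitive endoderm markers and Polycomb subunits (both adjusted p = 0.0246). This test does not compare a list with other genes. For p53 targets the pooled median was 0.02 and the pooled mean -0.02, with camera pointing lower, and for Polycomb subunits both were -0.02 with camera pointing higher.

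Set beside the random lists, several hairpin medians lay at the edge without a test behind them. With shRNA3387, 0 of 10000 random lists were at or below the p53 targets, 2 at or below the pluripotency factors, 4 at or below the two-cell-like genes and 14 at or above the hypoxia and glycolysis genes. With shRNA2863, 0 were at or below the integrated stress response genes, 2 at or below the proliferation genes, 8 at or below the imprinted genes and 2 at or above the germline genes.

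**Figure D3:**
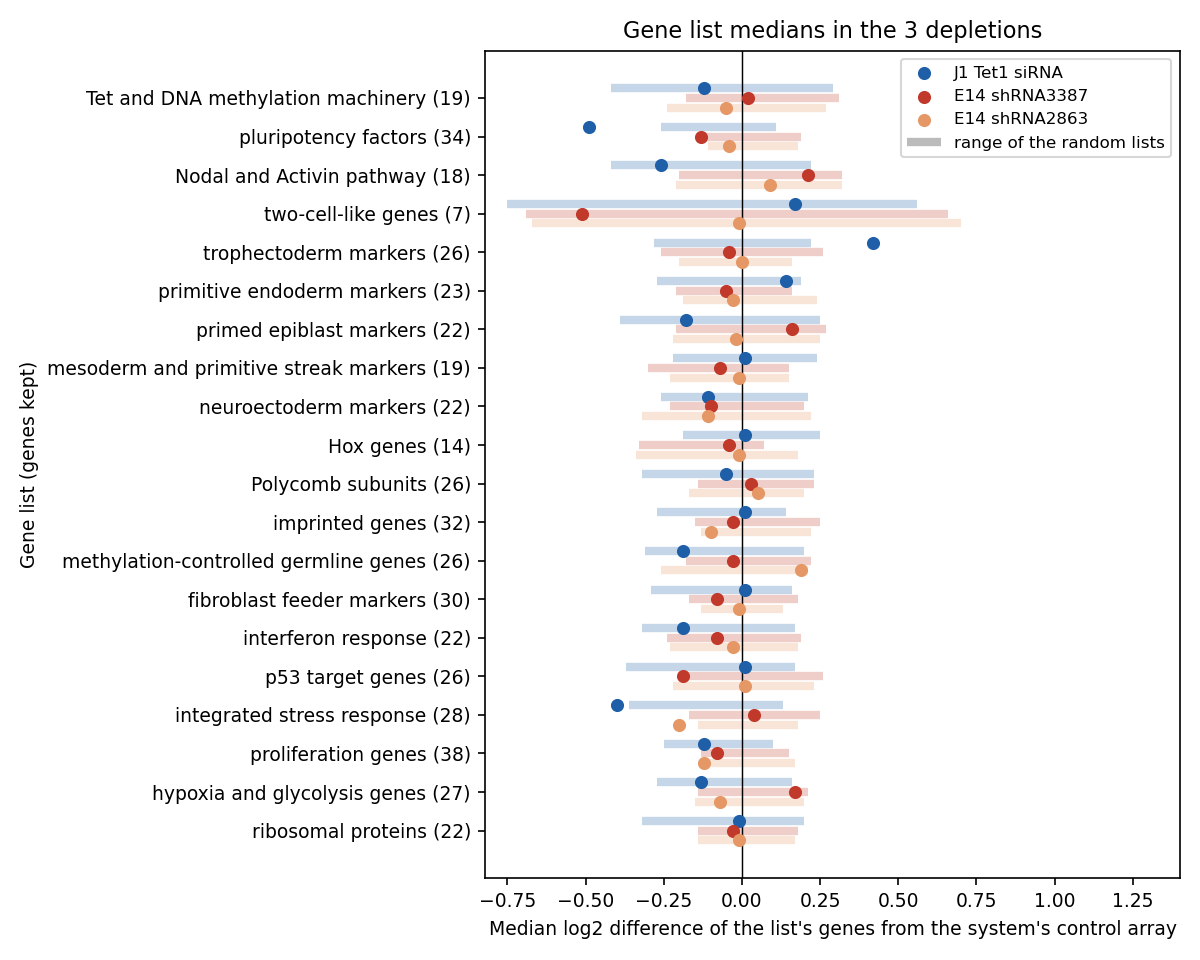
Median log2 difference from the control array of the same system (horizontal axis) for each fixed list (vertical axis, number of kept genes in parentheses), as 1 point per depletion; bars span the medians of 10000 level-matched random lists. In J1, pluripotency factors at -0.49 and integrated stress response genes at -0.40 lie below their bars, and trophectoderm markers at 0.42 above theirs.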

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

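All tests of explanations in this part were chosen after the results were seen. Bootstrap intervals resample genes read on the same single arrays, so they hold no variation between arrays or cultures. The effect of Tet1 depletion differed between the systems for 5 gene lists when camera with the preset correlation was run on the difference of effects, E14 minus J1. The median difference was 0.39 for pluripotency factors (adjusted p = 8.91e-06), 0.36 for the Nodal and Activin pathway (adjusted p = 0.00752) and 0.45 for methylation-controlled germline genes (adjusted p = 0.0109). With an estimated correlation each of these had an adjusted p of 0.85. That form of camera takes its degrees of freedom from the residuals, 1 in this fit, so it had little power to call a list. The median difference was -0.34 for trophectoderm markers (adjusted p = 0.0305) and -0.18 for primitive endoderm markers (adjusted p = 0.00326), and with an estimated correlation these too had an adjusted p of 0.85. Some of these lists already differed between the control arrays. For E14 scramble minus J1 control the trophectoderm median was -0.54, below all 10000 random lists. It was -0.12 for primitive endoderm markers, 0.32 for Nodal and Activin, -0.05 for pluripotency factors and 0.04 for germline genes.

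The pattern weighed first is the lower pluripotency factors and higher trophectoderm markers in J1 cells with Tet1 siRNA. A shift of genes by level on the array is argued against, since the lowest of 10000 level-matched random lists had a median of -0.26 against -0.49, and the highest for trophectoderm markers 0.22 against 0.42. A larger share of feeder fibroblasts is not excluded: the 30 fibroblast markers had a median of 0.01 (bootstrap 95% interval -0.09 to 0.06), under the rise of 0.32 needed of transcripts made by feeders alone at an assumed share of 50%, but only 10 of them were higher in J1 control than in feeder-free E14 scramble cells, and of these 6 were higher and 4 lower with Tet1 siRNA (median 0.15), while of 6 collagens 3 were lower (median -0.12). Deeper loss of Tet1 in J1, seen in 2 of the 3 Tet1 probe sets above the filter but not in the dimmest of them (-1.52 in J1 against -1.80 with shRNA3387), stays open, as do line, feeders, reagent and loss of Tet2, which differ together with it: inside E14, the hairpin with less Tet1 had pluripotency factors lower by a median of -0.05, with 670 of 10000 random lists at or below it, and 3 depletions cannot tell depth from system.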

How the results depend on the processing

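The alternatives were chosen before any result was seen, but the rule for when a value without a test counts as turned was set after, and pseudocounts were not run because the values are already log2. The fit over both systems sets each depletion against the control of its own system, and the setting without a system term is the unblocked alternative. Limma called 0 genes in all 3 comparisons under every setting run, and the pooled fit had 228 (no system term) to 1922 (without the scramble array) genes at an unadjusted p under 0.05. Under normalization, filter and probe set choices the J1 count was 201 to 231 against 214, the count with both hairpins 51 to 81 against 73, the count in all 3 depletions 5 or 6 against 6, the correlation between systems 0.09 to 0.15 against 0.11, and the Tet1 difference -1.85 to -1.82 against -1.83 (-1.70 without a system term). A 1.5-fold threshold raised the counts to 1226 in J1, 483 with both hairpins and 70 in all 3, by its construction. Lists passing camera were 6, or 5 with the median over probe sets and 4 without a system term, and 0 with an estimated correlation and 0 in fry.

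With each array left out in turn, Tet1 ran from -2.54 to -1.30, the correlation from 0.05 (without shRNA2863) to 0.15, lists passing from 0 (without either J1 array) to 6, and the count shared by the remaining depletions from 9 to 73, where 73 is the hairpin pair alone. Of 140 such values of named genes 134 kept their direction. Those that turned ran from -0.08 to 0.07 for Dnmt1, -0.19 to 0.02 for Dnmt3a, -0.07 to 0.33 for Dnmt3b and -0.35 to 0.02 for Sox2. Pooled list medians that turned ran from -0.26 to 0.15 for Nodal and Activin, -0.19 to 0.20 for two-cell-like genes, -0.02 to 0.42 for trophectoderm, -0.03 to 0.14 for primitive endoderm, -0.18 to 0.07 for primed epiblast, -0.04 to 0.01 for mesoderm, -0.03 to 0.01 for Hox, -0.05 to 0.04 for Polycomb, -0.10 to 0.01 for imprinted, -0.19 to 0.04 for germline, -0.06 to 0.02 for fibroblast, -0.07 to 0.09 for p53 and -0.14 to 0.06 for hypoxia genes. The trophectoderm shift is carried by the J1 arrays.

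Under the other settings 164 of 167 values of named genes and 110 of 120 list medians kept their direction and side of the threshold. The median over probe sets turned Atxn1 to -0.19, Stxbp5 to -0.24, Dnmt1 to -0.01, the E14 means of Insyn2a to -0.06 and Ptn to -0.04, and the Polycomb and ribosomal medians to 0.05 and 0.02; it averages in dimmer probe sets. The two-cell-like median became -0.01 without a filter, primed epiblast -0.01 and Hox 0.10 with the filter at the 60th percentile, and Nodal and Activin 0.05 and ribosomal 0.01 without a system term. J1 medians of 0.01 for fibroblast, Hox, imprinted, mesoderm and p53 lists became -0.03 with centred arrays, and those of Polycomb (-0.05) and ribosomal (-0.01) lists became 0.05 and 0.04 with the median over probe sets. None of these genes or lists passed limma or camera in the fit over both systems as reported, and the cause was not tested. Genes under the filter level of 3.03 to 3.12 on an array, such as Smc1b in E14, have signal that is hard to tell from background there.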

Other observations

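Of the tests in this part, the position of the J1 control relative to the E14 arrays was fixed before its result was seen, and the others were chosen afterwards. Bootstrap intervals here too resample genes on the same single arrays and hold no variation between arrays or cultures. Genes of chromosomes 8 and 11 were lower as a group in E14 than in J1 cells, with or without Tet1 depletion. Over 7098 genes with a mean over 6, placed on chromosomes by assembly GRCm38.p6, the 400 genes of chromosome 8 differed between the control arrays by a median that was -0.28 relative to the rest, and the 607 of chromosome 11 by -0.26. The other 18 chromosomes lay between -0.02 and 0.12. The same comparison between shRNA3387 and J1 Tet1 siRNA gave -0.28 and -0.26, and within a system the medians of all chromosomes relative to the rest lay between -0.07 and 0.06. A few strongly different genes would not move the share of lower genes, yet 76.8% of chromosome 8 genes and 74.5% of chromosome 11 genes were lower in E14 against 55.7% and 55.3% elsewhere, the smaller excess being 19.2 percentage points.

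A candidate explanation is a copy number difference, such as a gain of chromosomes 8 and 11 in the J1 culture, gains that mouse stem cells are known to acquire; it predicts a shift along the whole chromosome, and with each chromosome divided into 4 parts all 8 parts had medians of -0.48 to -0.26, below the lowest other whole chromosome at -0.11 and, narrowly, below all 72 parts of the other chromosomes, which ran from -0.25 to 0.28. The size is under the -0.58 that 2 copies against 3 would give in every cell with a linear array response. No DNA measurement was analysed here, and since the shift was noticed in these arrays, copy number remains a hypothesis. Loss in E14 cannot be separated from gain in J1 with these values.

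The 73 genes that differed at least 2-fold with both E14 hairpins may in part reflect the single scramble array. If that array stood apart, the J1 control should lie closer to the hairpins than to the scramble array at most of these genes, and it did at 47 of 73 (64.4%, bootstrap 95% interval 53.4% to 75.3%), against 54.8% of all kept genes, which falls between the outcomes fixed for and against this explanation. Hba-a2 is an example, at 6.11 with the scrambled hairpin, 3.40 and 3.35 with the Tet1 hairpins and 2.90 in J1 control cells. For a Tet1 effect shared with J1, the bar was a J1 median, signed by the E14 direction, above 0.67, set from the median E14 size of 1.33. The genes were picked for size against the shared scramble array, which inflates that E14 size. Falling short of the bar therefore does not by itself count against a shared effect. The value was 0.07 (bootstrap 95% interval -0.01 to 0.22), above 99.8% of 10000 random lists. Those lists were matched on mean level only, whereas the 73 genes were picked for large differences, so the percentile may be too high. The interval covers 0, so both a small shared part and none stay open. A second scramble array would be needed to separate these explanations.

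The 6 genes at least 2-fold different the same way in all 3 depletions were compared with the other choices of 1 control array per system. The largest count among these was 4, and 1 of the 6 choices, the real one, reached 6. With 6 choices a share under 0.05 cannot be had.

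Hprt was low on all 3 E14 arrays (4.38 to 4.43) and at 10.80 and 10.91 on the J1 arrays; widely used E14 sublines are known to lack Hprt. Over the 4983 unnamed or several-gene probe sets above the filter, 0 were at least 2-fold higher and 0 at least 2-fold lower in all 3 depletions.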
